A study of Mus musculus with 28 samples.

How the data were processed

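Transcript levels were measured by RNA sequencing in 28 mouse libraries that fall into 9 groups. Starting fibroblasts (MEF) came from C57BL/6 embryos taken 13.5 days after conception, and hepatocytes (Hep) from livers of mice 10 weeks old. The other cells had received retroviruses carrying Hnf4a and 1 member of the Foxa family, a set of transcription factors active in foregut and liver. Foxa1, Foxa2 and Foxa3 were each sampled at 48 h and again as established induced hepatocyte-like (iHep) cells. A Foxa3 mutant named del2 was sampled once, and its labels do not say which residues it lacks. The titles of those libraries give 48 h, their stage label says iHep, and the series description calls the cells iMEFs, a term it does not spell out. They were analysed as 48 h cells, with iHep_Foxa3 as a second comparator.

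According to the labels, the libraries were made with a stranded mRNA kit from RNeasy RNA. The submitters named BWA 0.7.12 and the mouse build mm9. The quantifier, its version, its settings and the annotation release are not given in the sources used here. For each of 30710 transcripts the deposited files hold an expected count, an FPKM value and a fraction of all reads, per the file headers and the values themselves. The FPKM recomputed from the expected counts and lengths differed from the deposited FPKM by at most 0.46% over transcripts with 1000 counts or more. At most 7 expected counts per file were not whole within 1e-09. Transcript identifiers were turned into gene symbols through RefSeq names for 30190 transcripts and through GENCODE for 181. The other 339 matched neither, took between 0.61% and 3.21% of a library's reads, and are not named here. The reference available was a later mouse build than mm9, so only names were taken from it and no coordinates are given.

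Expected counts were summed per gene to 23712 rows, rounded, and analysed in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr left 16499 genes. Library sizes were scaled by TMM. A quasi-likelihood model with robust settings held 1 coefficient per group over all 28 libraries, with 19 residual degrees of freedom, since most groups hold 2 libraries. Each of 21 comparisons was tested 2-sided with edgeR's F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, with no minimum fold. Levels are CPM from edgeR's cpm function on the scaled library size, given as mean ± SD over n libraries. Some log2 fold changes are given with a standard error. These p-values use within-group spread pooled over all 28 libraries, and iHep replicates varied more than 48 h ones. They do not show how cultures, embryos or virus batches differed.

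Assigned reads ranged from 14592820 to 51743266 per library. In a group with 0 counts a fold is given only as a lower bound, against a floor of 3 counts over the group. Where a group held 1 to 3 counts, levels alone are given. Reads carry no molecular identifiers, so floors cover counting error only.

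The choices in this paragraph were made before the data were examined. They were 28 gene lists holding 497 genes, of which 29 were not tested, the comparisons, the model and the alternatives. The lists covered the introduced factors, hepatic transcription factors, plasma proteins, coagulation and complement, lipoproteins, bile acids, xenobiotic metabolism, amino acid and urea metabolism, glucose, fatty acid oxidation, cholesterol and fatty acid synthesis, fetal liver, epithelium, mesenchymal matrix, mesenchymal transcription factors, cholangiocytes, intestine, stomach, lung, leukocytes with Kupffer cells, endothelium, stellate cells, erythroid cells, skeletal muscle, proliferation, cell-cycle inhibitors, interferon response and stress. Each list was tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Genes could be named for a comparison if they were an introduced factor. They could also be among the 8 largest rises or 8 largest falls of called genes whose groups did not overlap and whose higher mean was at least 5 CPM. For each list, up to 4 called members with the smallest adjusted p and up to 4 with the highest mean level could be named. Rows known only by an identifier are left out. Of the genes so eligible, the text names those that describe the lists best.

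The alternatives chosen before the data were seen were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma on log2(FPKM + 1) with a minimum of 1 in 2 libraries, no filter on low counts, the most abundant transcript of each gene, the 2 compared groups alone, the replicate number as a block, each library left out in turn, a 2-fold minimum for overlaps, and the other comparator for the mutant. Chosen after seeing the data were a term for the library set described in the results, the libraries of each set alone, and the 48 h and MEF libraries alone. DESeq2 size factors moved the median log2 fold change of all genes by 0.16 in Hep against MEF. They moved it by -0.21, -0.24 and -0.23 in iHep_Foxa1, iHep_Foxa2 and iHep_Foxa3 against Hep. Every other comparison moved by less than 0.1.

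The pipeline was tested on data simulated from each gene's level and spread. In 6 against 6 libraries, edgeR recovered 63% of 2-fold and 88% of 4-fold changes, with 7 false calls among 16289. In 2 against 2 it recovered 15% and 65%, with 2 among 16319. These rates may not hold with library sets or unequal group spread. Overlaps were compared with those under independence. In 8 simulated data sets without group differences at most 1 gene was called, too few for overlaps. Figures were drawn with Python 3.11.15.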

Results

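The series followed embryonic fibroblasts that received Hnf4a together with Foxa1, Foxa2 or Foxa3, a pairing used to turn fibroblasts into hepatocyte-like cells. RNA was sequenced from 2 libraries of untreated fibroblasts (MEF) and 2 of adult hepatocytes (Hep). For each Foxa factor there were 2 libraries at 48 h (48h_Foxa1, 48h_Foxa2, 48h_Foxa3). Established iHep cells gave 6 libraries with Foxa1, 4 with Foxa2 and 6 with Foxa3 (iHep_Foxa1, iHep_Foxa2, iHep_Foxa3). A further 2 libraries came from cells given Hnf4a with the Foxa3 mutant del2 (48h_Foxa3del2). These group sizes are the n behind every mean ± SD below. No library of cells given an empty virus or Hnf4a alone was among the 28, so an effect of infection cannot be separated from an effect of the factors.

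Depth differed between groups. Assigned reads numbered 34069974 to 43637300 in the 48 h libraries with full-length factors and 46620713 to 51743266 with the mutant. They numbered 17996416 to 31216564 in iHep_Foxa1, 25354288 to 30983889 in iHep_Foxa2 and 25580687 to 30178320 in iHep_Foxa3. MEF had 22039143 to 22178268 and Hep 14592820 to 15658619. Across genes, log levels of replicates correlated with r from 0.914 to 0.971 within iHep_Foxa1, 0.955 to 0.965 within iHep_Foxa2 and 0.948 to 0.982 within iHep_Foxa3. In every other group r was at least 0.976, and genes are not independent replicates.

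The libraries also fell into 2 sets that the groups do not explain. The small nuclear RNA 7SK (Rn7sk) lay between 17.2 and 72.5 CPM in 14 libraries and between 0 and 5.98 CPM in the other 14. The high set held the 6 libraries at 48 h with full-length factors, replicates 4, 5 and 6 of iHep_Foxa1 and replicates 2 to 6 of iHep_Foxa3. The low set held the rest, including all of MEF, Hep, iHep_Foxa2 and the mutant libraries. Rps29, a short ribosomal protein transcript, stood at 249 to 921 CPM in the high set and 23.8 to 60.5 CPM in the low set, apart from 372 and 373 CPM with the mutant. Inside iHep_Foxa1, where 3 libraries of each set can be compared, 5587 genes differed, 2383 higher and 3204 lower in the high set. Of 98 ribosomal protein genes, 76 were higher, while Junb, an immediate early gene, was lower (247 against 2118 CPM). Of the 5587 genes, 4572 (81.8%) went the same direction in iHep_Foxa3, where 5 high libraries face 1 low one. Comparing 48h_Foxa1, 48h_Foxa2 and 48h_Foxa3 with MEF, and the mutant with 48h_Foxa3, puts one set against the other. Values with a set term, chosen after seeing the data, are given too. By Rn7sk the mutant and MEF are both low, but by Rps29 only MEF is. Of the 2612 genes called between them, 1814 (69.4%) went the way high differs from low inside iHep_Foxa1.

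**Figure D1:**
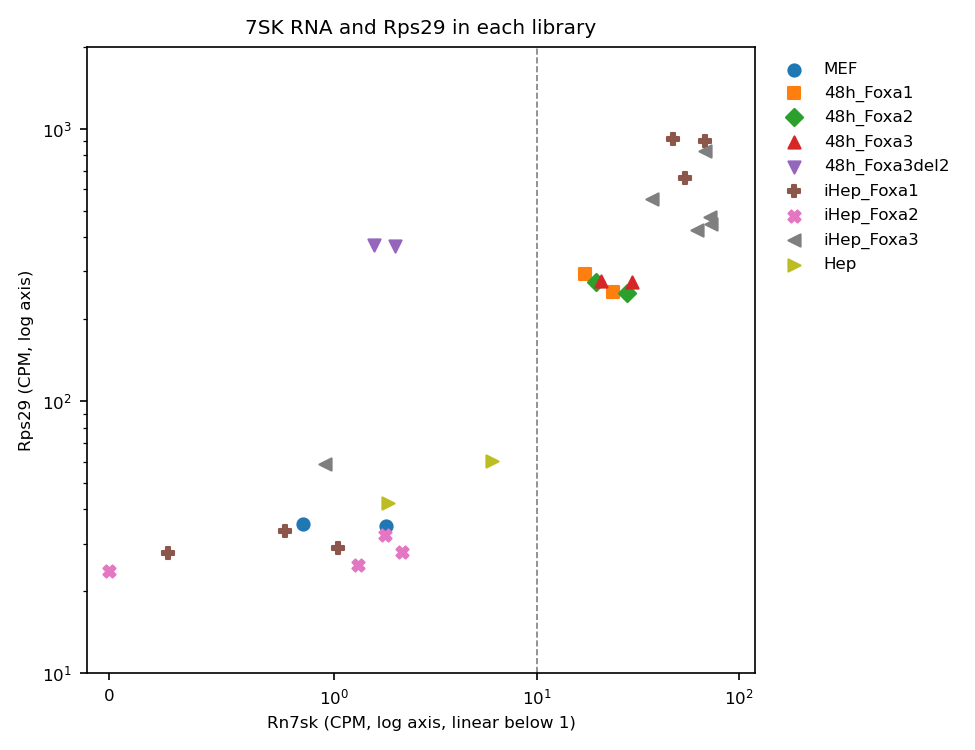
Each point is 1 library, placed by Rn7sk (x axis, CPM) and Rps29 (y axis, CPM) on log axes, with the groups as symbols and a dashed line at 10 CPM of Rn7sk. The 14 libraries to the right of the line lie between 17.2 and 72.5 CPM of Rn7sk and the other 14 between 0 and 5.98 CPM.

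Adult hepatocytes and fibroblasts mark the end points of the conversion, and the comparison shows which genes separate them. Hepatocytes carried liver-secreted and metabolic transcripts at levels far above those in fibroblasts. Albumin (Alb) made up 140000 ± 12620 CPM in Hep and 8.16 ± 0.503 CPM in MEF, and the iron carrier transferrin (Trf) 28030 ± 646 and 3.05 ± 1.13 CPM. Fibroblasts carried type I collagen (Col1a1, 22930 ± 3603 against 9.37 ± 1.98 CPM), smooth muscle actin (Acta2, 673 ± 12 against 0.247 CPM) and the fetal growth factor Igf2 (4530 ± 1023 against 1.47 ± 1.20 CPM). Of the introduced factors, hepatocytes held Hnf4a at 1006 ± 91.8 CPM, Foxa1 at 37.9 ± 3.03, Foxa2 at 104 ± 14.6 and Foxa3 at 157 ± 46.0.

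In Hep against MEF, 9387 of 16499 genes differed, 4005 higher and 5382 lower in Hep. The hepatic transcription factors were higher in 21 of 21 members, with Cebpa at 2047 CPM against 39.2 and Ppara, a regulator of fatty acid use, at 227 CPM against 1.03. Plasma proteins were higher in 25 of 25, coagulation and complement genes in 27 of 28, lipoprotein genes in 18 of 19, bile acid genes in 15 of 16 and xenobiotic genes in 23 of 23. Amino acid and urea genes were higher in 26 of 26, glucose genes in 11 of 11 and fatty acid oxidation genes in 11 of 12. Adjusted over the list alone the counts were the same, apart from 12 for fatty acid oxidation. From here on, a count given without a second value is the same adjusted over the list alone. Examples were Cps1, the entry enzyme of the urea cycle (log2 fold change 13.67 ± 2.37), the ethanol-metabolising Cyp2e1 (12.45 ± 0.95), the bile salt pump Abcb11 (12.36 ± 0.83) and Pck1 of gluconeogenesis (13.67 ± 1.56). Agxt and Acsm1 had no counts in MEF and were at least 10400-fold and 16400-fold higher in Hep. Penk, a neuropeptide precursor, had no counts in Hep and was at least 2110-fold lower. These list calls held with an estimated correlation, as did those for the introduced factors (4 of 4 higher, adjusted p = 0.012) and for endothelial genes (11 of 15 higher, adjusted p = 0.0029), among them the scavenger receptor Stab2 (29.1 against 0.143 CPM).

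The remaining lists called between Hep and MEF lost that call with an estimated correlation. Cholesterol and fatty acid synthesis genes were higher in 16 of 24 members and lower in 1, or 17 and 1 adjusted over the list alone (adjusted p = 0.00037, and adjusted p = 0.38 with an estimated correlation). The fatty acid desaturase Scd1 stood at 12290 ± 9394 CPM in Hep and 458 ± 86.2 in MEF, while Srebf2, the regulator of cholesterol synthesis, was lower (log2 fold change -1.49). Epithelial genes were higher in 18 of 30 and lower in 2 (adjusted p = 4e-05, and adjusted p = 0.26 with an estimated correlation), with Cdh1, the epithelial cadherin, at 41.6 against 0.191 CPM. Mesenchymal matrix genes were lower in 24 of 26 and mesenchymal transcription factors in 17 of 19, with 1 of the latter higher (adjusted p = 0.17 and adjusted p = 0.077 with an estimated correlation). Proliferation genes were lower in 25 of 26 (adjusted p = 0.17 with an estimated correlation), with Mki67 at 4.74 CPM in Hep and 109 in MEF. Cell-cycle inhibitors were lower in 10 of 12 and fetal liver genes in 7 of 10, with 1 higher in each list (adjusted p = 0.099 and adjusted p = 0.13 with an estimated correlation). Leukocyte and Kupffer cell genes were higher in 5 of 16 (adjusted p = 0.27 with an estimated correlation), with the macrophage gene Cd5l at 101 ± 25.8 CPM in Hep. Erythroid genes were higher in 2 of 3, including Klf1, and stellate cell genes in 4 of 10, without a call for either list (adjusted p = 0.22 and 0.16).

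The 48 h libraries address what the factors change first. Each introduced pair was present and specific, with Hnf4a at 67.2 ± 15.4, 72.5 ± 11.2 and 81.3 ± 8.18 CPM in 48h_Foxa1, 48h_Foxa2 and 48h_Foxa3 against 0.0952 ± 0.135 CPM in MEF. The delivered Foxa gene stood at 48.3 ± 3.06 CPM (Foxa1), 45.6 ± 0.19 CPM (Foxa2) and 72.4 ± 6.71 CPM (Foxa3), against at most 0.718 CPM in a MEF library. Epithelial cadherin rose with all 3 factors, Cdh1 reaching 5.42 ± 0.948, 4.98 ± 0.418 and 7.58 ± 1.17 CPM against 0.191 CPM in MEF. The transporter Abcc6 was at 5.16, 5.25 and 5.48 CPM against 3 counts in MEF, and the retinol carrier Rbp4 rose by log2 fold changes of 3.04, 3.07 and 2.62. The hepatic transcription factors stayed uncalled (0 of 21 members with edgeR, 4, 3 and 3 higher and 1 lower at an unadjusted p under 0.05, and 0, 0 and 1 with DESeq2). Hnf4a, Cdh1 and Abcc6 kept their calls without any 1 library, and that of Cdh1 ended with limma on FPKM (adjusted p from 0.0634 to 0.159). Rbp4 lost its call without MEF replicate 2 with Foxa1 (0.0516) and without 48h_Foxa3 replicate 1 or 2 or MEF replicate 2 with Foxa3 (0.0517 to 0.0829). The delivered Foxa1 lost its call without MEF replicate 2 (0.0688) and the delivered Foxa2 without MEF replicate 1 or 2 (0.0547 and 0.0745).

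The number of genes called against MEF at 48 h was 867 with Foxa1 (352 higher, 515 lower), 904 with Foxa2 (363 and 541) and 859 with Foxa3 (367 and 492). Stress and immediate early genes fell in 6, 6 and 5 of 18 members, or 8, 7 and 8 adjusted over the list alone. Their adjusted p was 2.1e-05, 6.3e-05 and 2.8e-05, or adjusted p = 0.34, 0.38 and 0.32 with an estimated correlation. Among them Ddit3, a factor of the unfolded protein response, fell from 126 ± 12.1 CPM to 28.9, 29.8 and 27.2 CPM, and Junb from 804 ± 600 CPM to 29.9, 38.1 and 30.5 CPM. Proliferation genes rose in 2 of 26 members with each factor, or 5 adjusted over the list alone (adjusted p = 0.00038, 0.00054 and 0.00045, and adjusted p = 0.76, 0.75 and 0.68 with an estimated correlation). Mki67 reached 311 ± 18.2, 328 ± 17.6 and 303 ± 5.62 CPM against 109 ± 2.99. Leukocyte genes fell in 5 of 16 members with each factor, or 11, 6 and 11 adjusted over the list alone (adjusted p = 1.3e-05, 0.00011 and 4.9e-05, and adjusted p = 0.28, 0.38 and 0.32 with an estimated correlation). The complement gene C1qc stood at 0.401, 0.584 and 0.465 CPM against 81.2 ± 99.7 CPM in MEF. All 12 leukocyte genes above 1 CPM in a MEF library were higher in MEF replicate 2 than in replicate 1, by a median of 12.5 times. Junb and Mki67 lost their calls without any 1 of the 4 libraries, that is replicate 1 or 2 of the 48 h group or of MEF (adjusted p from 0.0707 to 0.268 and from 0.146 to 0.231). Ddit3 lost its call without replicate 1 or 2 of 48h_Foxa1 or 48h_Foxa2, or replicate 2 of 48h_Foxa3 (0.0552 to 0.0789). C1qc lost its call without 48h_Foxa1 replicate 2, 48h_Foxa2 replicate 1 or 2 or 48h_Foxa3 replicate 2 (0.0517 to 0.0645), and its log2 fold change moved from -7.67, -7.11 and -7.44 to -4.68, -4.13 and -4.46 without MEF replicate 2. C1qc, Junb and Mki67 lost their calls with each factor once a term for the library set was added (0.11 to 0.29). With Foxa1 the log2 fold change of Junb shrank from -4.75 ± 1.25 to -1.90 ± 0.70, while that of C1qc went from -7.67 ± 1.05 to -6.36 ± 3.14 and that of Mki67 from 1.51 ± 0.42 to 1.30 ± 0.49. With no filter on low counts Junb lost its call with Foxa2 (0.0518).

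The cholesterol and fatty acid synthesis list was called lower at 48 h (adjusted p = 0.00076, 0.0012 and 0.0015, and adjusted p = 0.76, 0.75 and 0.68 with an estimated correlation). None of its 24 members was called by edgeR, 6, 7 and 7 were lower at an unadjusted p under 0.05, and DESeq2 called 2, 2 and 1. Scarb1, the lipoprotein receptor that takes up cholesterol esters, fell from 59.8 ± 8.13 CPM to 25.4, 24.8 and 26.0 CPM. It lost its call without 48h_Foxa1 replicate 1 or 2, 48h_Foxa2 replicate 1 or 2, 48h_Foxa3 replicate 1 or 2, or MEF replicate 2 (adjusted p from 0.0977 to 0.17). With the library set as a term it lost it with Foxa1 and Foxa3 (0.0594 and 0.0667), where its log2 fold change went from -1.23 ± 0.25 to -0.90 ± 0.26 and from -1.20 ± 0.25 to -0.86 ± 0.26. Plasma protein and amino acid genes that fell at 48 h (Itih1 and Gc, and Hpd, Mat1a and Bhmt) averaged at most 0.668 CPM in MEF. All are among the 78 liver genes with traces in MEF (last paragraph), so their fall is not shown to be repression. Their calls ended without any 1 of the 4 libraries, apart from Gc with Foxa1 and Foxa2 without MEF replicate 1. With a set term all of them ended (0.0508 or more), which decides nothing, as these genes have almost no counts outside MEF and Hep. With DESeq2 the calls of Hpd and Bhmt (0.574 to 0.645), of Mat1a with Foxa1 (0.0563) and of Gc with Foxa3 (0.0844) ended, and with limma on FPKM those of Itih1 and Mat1a (0.145 to 0.671). The introduced factor list was called with Foxa3 (adjusted p = 0.0066, and adjusted p = 0.11 with an estimated correlation). The counts of called genes depended on the libraries fitted. They fell sharply without any 1 library, which leaves 1 in a group, and were 5697, 5738 and 5810 with the compared groups alone. With a term for the library set 529, 646 and 604 genes were called, of which 213, 246 and 228 went the same way as without it. Of the calls without that term (867, 904 and 859), 76.6%, 76.3% and 76.7% went the way the high set differs from the low set inside iHep_Foxa1.

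**Figure D2:**
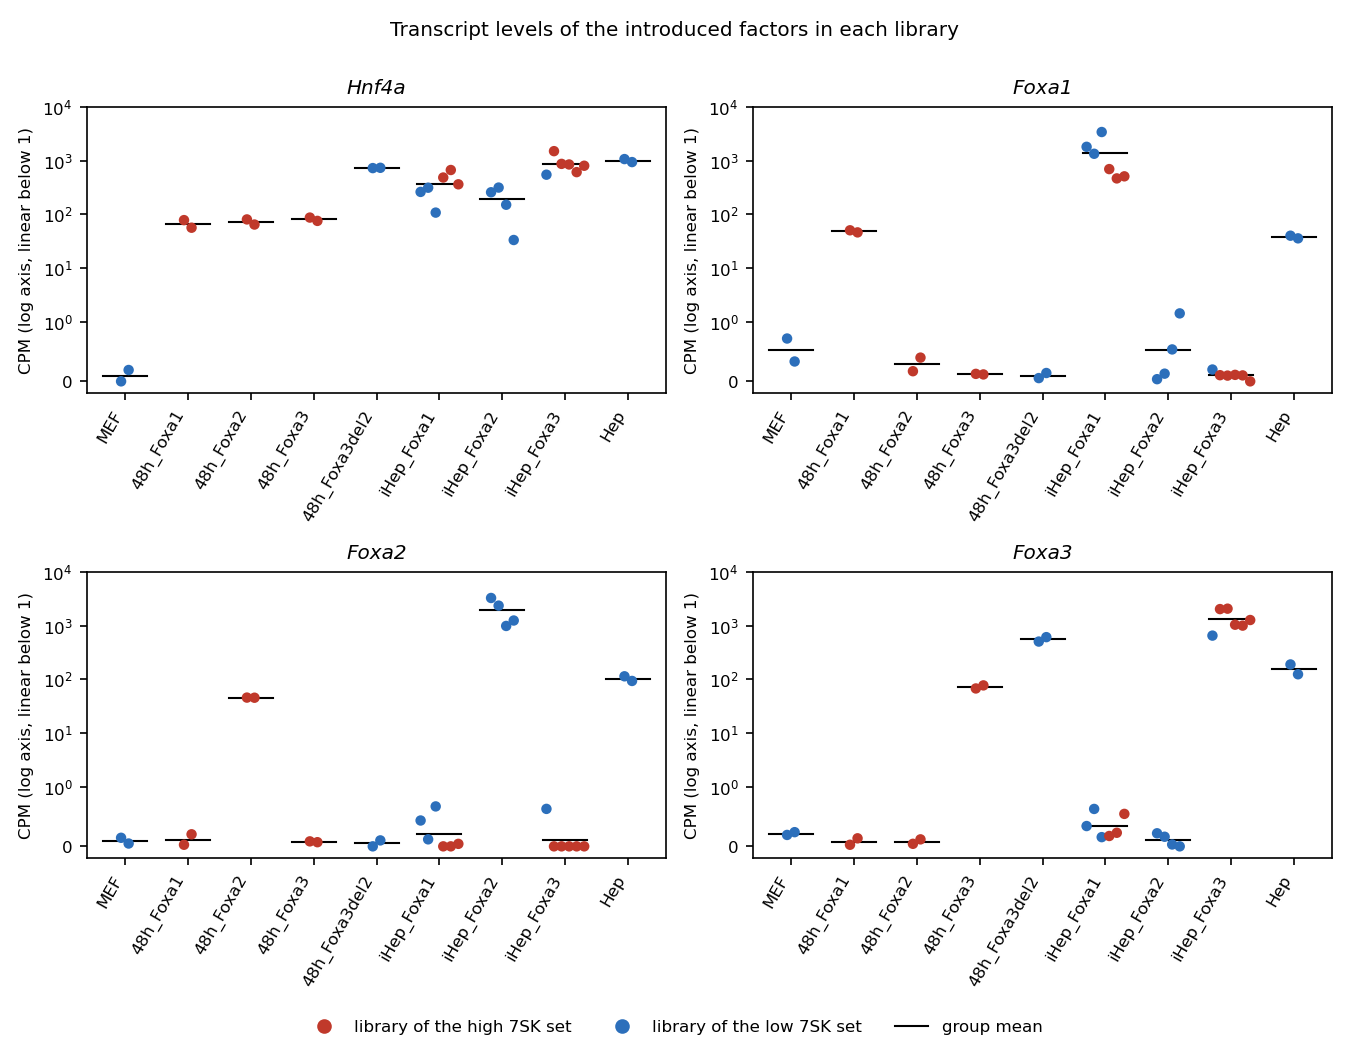
Levels of Hnf4a, Foxa1, Foxa2 and Foxa3 in each library (y axis, CPM on a log axis that is linear below 1), with groups along the x axis, 1 point per library coloured by 7SK set and a black bar at the group mean. The delivered Foxa gene lies between 45.6 and 72.4 CPM on average at 48 h with full-length factors, at 559 CPM with the mutant and between 1347 and 1971 CPM in iHep cells, and Hnf4a lies between 67.2 and 81.3 CPM at 48 h with full-length factors and at 732 CPM with the mutant.

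Setting the 48 h groups against each other asked whether the Foxa proteins differ early. The only genes called were the delivered factors themselves. Between 48h_Foxa1 and 48h_Foxa2, 1 gene was called, Foxa1 (48.3 against 0.284 CPM, adjusted p = 0.031), while Foxa2 at 0.115 against 45.6 CPM had adjusted p = 0.074. Foxa1 and Foxa3 made up the 2 genes between 48h_Foxa1 and 48h_Foxa3, and Foxa2 and Foxa3 the 2 between 48h_Foxa2 and 48h_Foxa3. At an unadjusted p under 0.05 there were 39, 15 and 33 genes, and DESeq2 called 2, 2 and 3. The introduced factor list was called lower in 48h_Foxa1 against 48h_Foxa3 (adjusted p = 0.0089, median 0.17, mean -0.19) and in 48h_Foxa2 against 48h_Foxa3 (adjusted p = 0.00056, median 0.51, mean 0.10), where its members go opposite ways. Both held with an estimated correlation. Leukocyte genes were called lower in 48h_Foxa1 than in 48h_Foxa2 and than in 48h_Foxa3 (adjusted p = 0.04 in both, and adjusted p = 1 and 0.87 with an estimated correlation), with 0 of 16 members called by edgeR, 0 at an unadjusted p under 0.05 and 0 with DESeq2. Without any 1 of the 4 libraries Foxa1 lost its call against 48h_Foxa2 (0.0927 to 1), as did Foxa2 against 48h_Foxa3 (0.118 to 1), and without 48h_Foxa3 replicate 1 or 2 Foxa1 lost its call against 48h_Foxa3 (0.724 to 0.728), leaving 1 gene there.

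Cells with the Foxa3 mutant were compared with full-length Foxa3 to ask what the deletion alters. They held more of both introduced transcripts, Hnf4a at 732 ± 6.5 CPM against 81.3 ± 8.18 and Foxa3 at 559 ± 74.7 against 72.4 ± 6.71. Apoa1, the main protein of high-density lipoprotein, was at 484 ± 17.5 CPM against 2.45 ± 0.773, and the transcription factor Zbtb16 at 41.6 against 0.668 CPM. The matrix proteoglycan gene Lum was lower (6.94 ± 1.21 against 408 ± 0.811 CPM), as was Penk (15.1 against 1733 CPM). The cells also differed in sex-linked transcripts. Xist, which silences the second X chromosome in female cells, was at 0.146 and 0.160 CPM with the mutant and at 585 to 1980 CPM in the other 26 libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no counts in 48h_Foxa3 and were at least 3710-fold, 1900-fold, 1340-fold and 922-fold higher with the mutant. Without any 1 of the 4 libraries (48h_Foxa3 replicate 1 or 2, mutant replicate 1 or 2) Hnf4a, Foxa3, Eif2s3y, Kdm5d and Uty lost their calls (adjusted p from 0.063 to 0.275), and Penk without mutant replicate 1 (0.0546), whereas Xist, Ddx3y, Apoa1, Zbtb16 and Lum kept theirs. The call of Lum ended with a term for the library set (0.117), because the standard error grew while the log2 fold change stayed, from -5.88 ± 0.69 to -5.90 ± 2.67. The Y-linked genes were below 1 CPM in all libraries but those of the mutant, so the set term has no counts to rest on and its adjusted p of 1 for each of the 4 decides nothing about them. With DESeq2 the calls of Eif2s3y, Kdm5d and Uty ended (0.311 to 0.363).

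In all, 491 genes differed between the mutant and 48h_Foxa3, 231 higher and 260 lower. Epithelial genes were higher in 3 of 30 members, or 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0055, and adjusted p = 0.84 with an estimated correlation), with the junction protein gene F11r at 51.0 against 22.0 CPM and the keratin gene Krt18 at 30.2 against 3.51 CPM. Matrix genes were lower in 1 of 26, or 2 adjusted over the list alone (adjusted p = 0.044, and adjusted p = 0.84 with an estimated correlation). Leukocyte genes were higher in 1 of 16, C1qc at 6.08 against 0.465 CPM, or 4 adjusted over the list alone (adjusted p = 0.00097, and adjusted p = 0.70 with an estimated correlation). Of mesenchymal transcription factors, Osr2 was lower (7.55 against 33.9 CPM). Without 48h_Foxa3 replicate 1 or 2, or mutant replicate 1 or 2, the count was 76, 74, 49 and 83 genes, and F11r, Krt18, C1qc and Osr2 each lost their calls without any 1 of the 4 (adjusted p from 0.0605 to 0.364). Against iHep_Foxa3 in place of 48h_Foxa3 the mutant cells differed in 5387 genes. With a term for the library set 3810 genes were called, and the call of C1qc ended (0.643), its log2 fold change going from 3.70 ± 0.89 to 2.38 ± 3.16, as it did with a replicate block (0.0733) and with 48 h and MEF libraries alone (0.0687).

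Against MEF the mutant cells differed in 2612 genes, 1284 higher and 1328 lower. Fatty acid oxidation genes were higher in 6 of 12 members, or 7 adjusted over the list alone (adjusted p = 0.005, and adjusted p = 0.62 with an estimated correlation). They included Cpt1a, which admits fatty acids to mitochondria (174 ± 5.92 against 64.1 ± 7.68 CPM), and Pdk4 (53.3 against 8.79 CPM). Cholesterol and fatty acid synthesis genes were lower in 10 of 24, or 12 adjusted over the list alone (adjusted p = 2.8e-05, and adjusted p = 0.75 with an estimated correlation). Insig1 was at 91.8 against 788 ± 436 CPM and the sterol demethylase Cyp51 at 128 against 790 ± 276 CPM. Epithelial genes were higher in 7 of 30, or 8 adjusted over the list alone (adjusted p = 9e-05, and adjusted p = 0.75 with an estimated correlation). Matrix genes were lower in 2 of 26, stress genes in 3 of 18, and proliferation genes higher in 2 of 26, or 1, 3 and 2 adjusted over the list alone (adjusted p = 0.029, 0.029 and 0.005, and adjusted p = 0.82 for all 3 with an estimated correlation). Col5a3 fell from 1280 ± 276 to 11.6 CPM, Ddit3 from 126 to 20.4 CPM, and Rrm2, which makes DNA precursors, rose from 71.8 to 239 CPM. Of secreted liver proteins, ceruloplasmin (Cp) rose from 2.46 to 33.3 CPM, and the introduced factor list was called (adjusted p = 0.017, and adjusted p = 0.20 with an estimated correlation). Without MEF replicate 1 or 2, or mutant replicate 1 or 2, the count was 1330, 752, 725 and 783 genes, and without MEF replicate 2 Cpt1a, Pdk4 and Rrm2 lost their calls (0.0664, 0.0926 and 0.0787). Insig1 and Cyp51 lost theirs without MEF replicate 2 or mutant replicate 1 or 2 (0.0662 to 0.0856 and 0.1 to 0.121), while a term for the library set gave 4829 genes.

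Established iHep cells were set against the fibroblasts they came from. Apoa1 reached 11980 ± 9886 CPM in iHep_Foxa1, 3563 ± 1966 in iHep_Foxa2 and 16100 ± 4344 in iHep_Foxa3, against 0.429 ± 0.0656 CPM in MEF. Cdh1 reached 594 ± 238, 604 ± 282 and 406 ± 213 CPM against 0.191 CPM. Col1a1 fell from 22930 ± 3603 CPM to 91.5 ± 93.8, 201 ± 95.1 and 22.4 ± 11.6 CPM. Hnf4a stood at 367 ± 194, 189 ± 124 and 865 ± 340 CPM, and the delivered gene at 1375 ± 1131 (Foxa1), 1971 ± 1058 (Foxa2) and 1347 ± 584 CPM (Foxa3). Within iHep_Foxa1, Foxa1 was at 1345 to 3419 CPM in the 3 libraries of the low set and 467.5 to 697 CPM in the 3 of the high set.

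Against MEF, 6586 genes differed in iHep_Foxa1 (3297 higher, 3289 lower), 5068 in iHep_Foxa2 (2518 and 2550) and 7689 in iHep_Foxa3 (3781 and 3908). Hepatic transcription factors rose in 11, 8 and 10 of 21 members, or 12, 8 and 10 adjusted over the list alone (adjusted p = 0.0045, 0.0019 and 0.0055, and adjusted p = 0.22, 0.21 and 0.27 with an estimated correlation). Gata4 was one of them (30.3, 11.5 and 10.7 CPM against 0.0956). Plasma proteins rose in 13, 12 and 11 of 25 and fell in 3 each, or 14, 13 and 11 with 3, 4 and 3 adjusted over the list alone (adjusted p = 0.001, 0.022 and 0.013, and adjusted p = 0.22, 0.38 and 0.45 with an estimated correlation). Cp rose by log2 fold changes of 7.74, 8.36 and 6.74, Trf by 6.94, 6.31 and 9.23, and fetuin (Ahsg) by 9.49, 8.43 and 10.62. The 3 plasma protein genes that fell in each comparison were all below 1 CPM in MEF. Coagulation and complement genes rose in 10, 7 and 7 of 28, and fell in 2, 1 and 2, or 2 each adjusted over the list alone. The list was not called (adjusted p = 0.14, 0.38 and 0.31), with the fibrinogen chain Fgb at 1848 ± 1149, 105 ± 63.4 and 2092 ± 1394 CPM against 0.668. Xenobiotic genes rose in 8, 6 and 5 of 23 and fell in 0, 1 and 1 (adjusted p = 0.10, 0.15 and 0.35), including the sulfotransferase Sult1a1 (65.1, 57.7 and 88.6 CPM against 0.143).

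Metabolic lists split. Fatty acid oxidation genes rose in 8, 7 and 10 of 12, or 10, 7 and 10 adjusted over the list alone (adjusted p = 0.001, 0.043 and 0.0037, and adjusted p = 0.22, 0.38 and 0.30 with an estimated correlation). Pdk4, a brake on glucose oxidation, rose from 8.79 CPM to 437, 640 and 169 CPM. Genes of cholesterol and fatty acid synthesis fell in 18, 22 and 11 of 24, or 19, 24 and 11 adjusted over the list alone (adjusted p = 3.4e-06, 9.4e-15 and 0.0045, and adjusted p = 0.33, 0.21 and 0.63 with an estimated correlation). Mvk was at 14.8, 10.7 and 20.6 CPM against 59.3 and Acly at 151, 137 and 197 CPM against 474. Amino acid and urea genes went both ways, with 6, 4 and 6 of 26 higher and 10, 5 and 9 lower, or 10, 9 and 9 lower adjusted over the list alone. The list was not called (adjusted p = 0.46, 0.25 and 0.42). Of the lower genes 7, 2 and 7 were below 1 CPM in MEF. Ass1 of the urea cycle fell from 242 ± 112 CPM to 14.6, 24.6 and 17.7 CPM. Its log2 fold change in iHep_Foxa3 went from -3.78 ± 0.52 to -2.63 ± 0.98 (adjusted p = 0.0749) with the low set alone, where that group is 1 library. Glutamine synthetase (Glul) rose from 30.3 to 990, 1219 and 792 CPM. Bile acid genes rose in 3, 4 and 3 of 16 and fell in 3, 1 and 3. Glucose genes rose in 4, 1 and 2 of 11 and fell in 1, 2 and 3, or 1, 2 and 2 adjusted over the list alone. Neither list was called (adjusted p = 0.64, 0.96 and 0.74, and 0.46, 0.98 and 0.68). Cyp27a1, which oxidises cholesterol side chains, rose from 1.15 to 91.8, 29.6 and 74.7 CPM. Fetal liver genes rose in 3, 1 and 3 of 10 and fell in 2, 3 and 5, or rose in 3, 2 and 4 and fell in 2, 4 and 5 adjusted over the list alone, without a call (adjusted p = 0.99, 0.70 and 0.77).

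**Figure D3:**
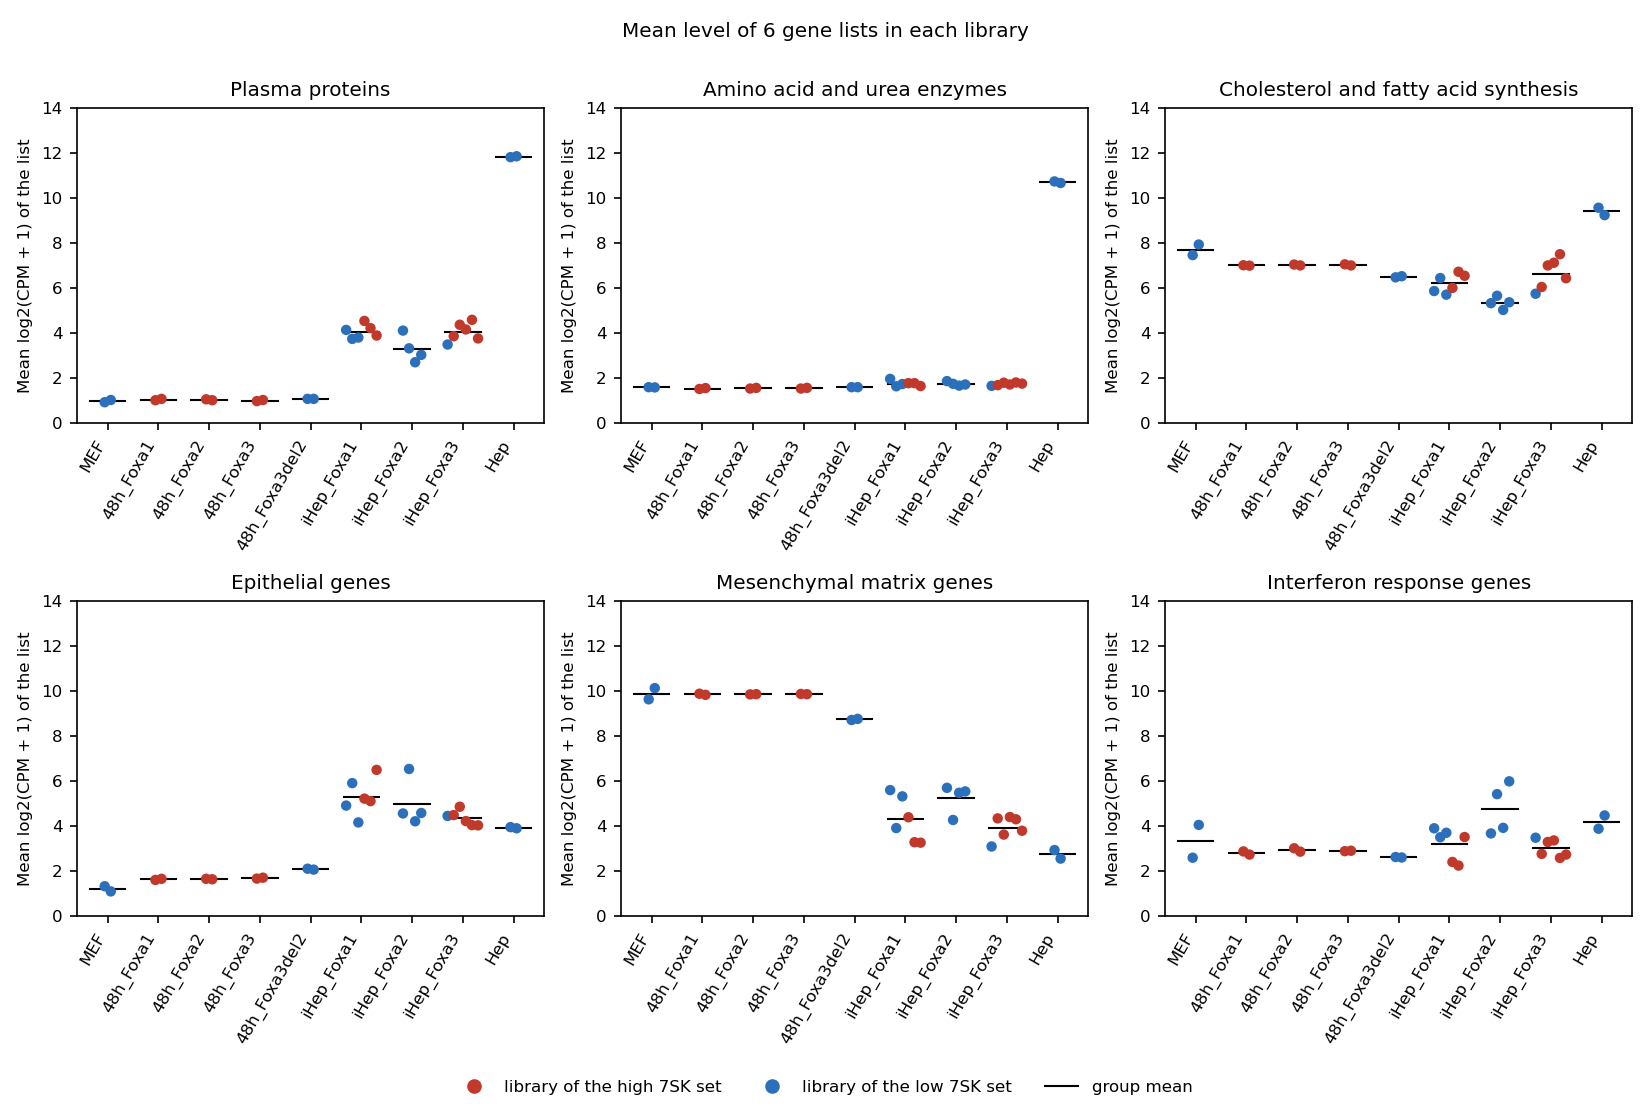
Mean log2(CPM + 1) over the members of 6 gene lists (y axis) in each library, with groups along the x axis, 1 point per library coloured by 7SK set and a black bar at the group mean. Matrix genes lie between 3.09 and 5.70 in the iHep libraries and at 9.64 and 10.1 in MEF, and amino acid and urea genes stay between 1.62 and 1.95 in iHep libraries and at 10.7 and 10.8 in Hep.

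Epithelial and mesenchymal lists moved in opposite directions against MEF. Epithelial genes rose in 26, 28 and 23 of 30, or 27, 29 and 23 adjusted over the list alone (adjusted p = 7.1e-14, 6e-15 and 1.4e-10, and adjusted p = 0.13, 0.21 and 0.27 with an estimated correlation). F11r rose by log2 fold changes of 4.06, 3.51 and 3.46, and Krt19, a keratin of bile duct and gut epithelium, by 5.48, 5.13 and 4.45. Matrix genes fell in 23, 20 and 25 of 26, or 23, 22 and 25 adjusted over the list alone (adjusted p = 2e-17, 1.5e-14 and 9.7e-15, and adjusted p = 0.093, 0.21 and 0.21 with an estimated correlation). Mesenchymal transcription factors fell in 14, 8 and 17 of 19 (adjusted p = 8e-06, 0.0025 and 1.8e-05, and adjusted p = 0.093, 0.24 and 0.21 with an estimated correlation). Col3a1 fell by log2 fold changes of -9.14, -9.22 and -10.80.

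Transcripts of other digestive epithelia were present too. Intestinal genes rose in 9, 7 and 8 of 16 and fell in 2 each, or rose in 9, 7 and 9 adjusted over the list alone, called for iHep_Foxa1 (adjusted p = 0.049, and adjusted p = 0.40 with an estimated correlation) and not for the others (adjusted p = 0.11 and 0.25). Gastric genes rose in 5, 5 and 3 of 9, or 8, 5 and 4 adjusted over the list alone, and 1 fell in each group, without a call (adjusted p = 0.11, 0.083 and 0.21). The goblet cell gene Clca1 and the gastric peptide gene Tff1 had no counts in MEF. Clca1 was at least 25200-fold, 13500-fold and 11600-fold higher in iHep_Foxa1, iHep_Foxa2 and iHep_Foxa3, and Tff1 at least 3870-fold, 2130-fold and 1530-fold. The gut lectin gene Lgals4 stood at 756 ± 855, 112 ± 118 and 93.9 ± 39.4 CPM against 1 CPM, while Lgr5, a stem cell receptor on the same list, fell from 52.5 ± 51.9 to 0.587, 0.779 and 0.376 CPM. Cholangiocyte genes rose in 7, 6 and 5 of 13 and fell in 3, 1 and 3, without a call (adjusted p = 0.22, 0.12 and 0.34). Lung genes rose in 3, 4 and 2 of 9, or 2, 6 and 1 adjusted over the list alone, called for iHep_Foxa2 (adjusted p = 0.045, and adjusted p = 0.46 with an estimated correlation).

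Leukocyte genes fell in 12 of 16 in each iHep group and 1 rose (adjusted p = 5.6e-05, 1.1e-05 and 0.001, and adjusted p = 0.30, 0.24 and 0.45 with an estimated correlation). The receptor Csf1r stood at 0.0289, 0.0236 and 0.0379 CPM against 7.45 ± 7.70 in MEF, where MEF replicate 1 held 2.01 and replicate 2 held 12.9 CPM. The riser was Cd14, a receptor for bacterial lipopolysaccharide, at 71.5 ± 41.2, 31.3 ± 27.9 and 91.5 ± 39.1 CPM against 2.31 ± 1.85, and without MEF replicate 1 its call in iHep_Foxa2 ended (adjusted p = 0.0524). Interferon genes rose in 8 of 25 in iHep_Foxa2 (adjusted p = 0.0042, and adjusted p = 0.53 with an estimated correlation), and 10 fell and 3 rose in iHep_Foxa3 without a call for the list (adjusted p = 0.68). The introduced factor list was called in iHep_Foxa1 (adjusted p = 0.035, and adjusted p = 0.13 with an estimated correlation). Ddit3 fell from 126 to 12.5, 16.9 and 16.6 CPM, one of 3 stress genes of 18 to fall in each group, where 1, 1 and 0 rose, or 0, 1 and 0 adjusted over the list alone, without a call for the list (adjusted p = 0.61, 0.96 and 0.29). Of 5 skeletal muscle genes 1 fell in each group and 1 rose in iHep_Foxa1 and in iHep_Foxa3, without a call (lowest adjusted p = 0.87), and endothelial and stellate lists were not called (lowest adjusted p = 0.084 and 0.41).

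Hepatocyte transcripts varied between iHep libraries of 1 group, as shown by Alb and Afp, chosen after their values were seen. Alb ranged from 51.8 to 1683 CPM in iHep_Foxa1, from 3.04 to 914 CPM in iHep_Foxa2 and from 10.9 to 163 CPM in iHep_Foxa3. The fetal form Afp ranged from 1.65 to 301 CPM in iHep_Foxa1. Without MEF replicate 1 or 2 the counts against MEF were 4305 and 3930 in iHep_Foxa1, 3177 and 2905 in iHep_Foxa2 and 5318 and 4858 in iHep_Foxa3, and with the low set alone iHep_Foxa3, then 1 library, gave 3990.

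Comparing iHep cells with their own 48 h stage shows what was gained later. Apoa1 went from 2.52, 1.41 and 2.45 CPM at 48 h to the levels given above (log2 fold changes 12.21, 11.30 and 12.68 for Foxa1, Foxa2 and Foxa3). The pancreatic trypsin inhibitor Spink1 went from 0.271, 0.0575 and 0.229 CPM to 3647 ± 3228, 202 ± 145 and 4058 ± 1787 CPM. The delivered Foxa gene rose by 4.83, 5.43 and 4.22. Hnf4a rose with Foxa1 and Foxa3 (2.45 and 3.41), and with Foxa2 it was at 189 ± 124 against 72.5 ± 11.2 CPM (adjusted p = 0.10). Without 48h_Foxa1 replicate 1 or 2 Hnf4a lost its Foxa1 call (adjusted p from 0.0507 to 0.0953), and without iHep_Foxa2 replicate 4 it gained one with Foxa2 (0.0207). All iHep_Foxa2 libraries belong to the low set and both 48h_Foxa2 libraries to the high set, and a term for the set turned the 5.43 ± 1.17 of Foxa2 to -0.46 ± 0.63 (adjusted p = 0.62). This decides nothing, as the iHep_Foxa1 and iHep_Foxa3 libraries that inform the term hold at most 0.67 CPM of Foxa2.

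From 48 h to iHep, 6926 genes differed with Foxa1 (3506 higher, 3420 lower), 6619 with Foxa2 (3363 and 3256) and 6696 with Foxa3 (3235 and 3461). Plasma proteins rose in 16, 13 and 15 of 25 and fell in 0, or rose in 18, 14 and 15 and fell in 0, 1 and 0 adjusted over the list alone (adjusted p = 3e-05, 0.0005 and 0.00016, and adjusted p = 0.15, 0.28 and 0.23 with an estimated correlation). Ahsg rose by 11.06, 10.13 and 13.62 and Trf by 6.23, 5.37 and 7.98. Hepatic transcription factors rose in 11, 8 and 8 of 21 and fell in 1, 0 and 1, or rose in 12, 9 and 8 adjusted over the list alone (adjusted p = 0.016, 0.016 and 0.014, and adjusted p = 0.25, 0.28 and 0.25 with an estimated correlation). Nr1h3, a sterol sensor, rose by 3.42, 3.20 and 3.48. Coagulation genes rose in 13, 8 and 9 of 28 and fell in 1, 0 and 2, called with Foxa1 and Foxa3 (adjusted p = 0.035 and 0.045, and adjusted p = 0.15 and 0.23 with an estimated correlation). Xenobiotic genes rose in 10, 8 and 6 of 23 and fell in 0, 0 and 1, called with Foxa1 and Foxa2 (adjusted p = 0.035 and 0.045, and adjusted p = 0.25 and 0.29 with an estimated correlation). Lipoprotein genes rose in 8, 6 and 6 of 19, and fell in 1, 2 and 1, or 2, 3 and 1 adjusted over the list alone, called with Foxa3 (adjusted p = 0.03, and adjusted p = 0.25 with an estimated correlation). Fatty acid oxidation genes rose in 7, 4 and 7 of 12 and fell in 0, 2 and 0, called with Foxa1 and Foxa3 (adjusted p = 0.03 and 0.036, and adjusted p = 0.35 and 0.41 with an estimated correlation).

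Epithelial genes rose from 48 h to iHep in 25, 27 and 22 of 30, or 27, 28 and 24 adjusted over the list alone (adjusted p = 1.2e-11, 2.9e-11 and 1.2e-09, and adjusted p = 0.15, 0.28 and 0.23 with an estimated correlation). Matrix genes fell in 26, 20 and 26 of 26, or 26, 22 and 26 adjusted over the list alone (adjusted p = 3.5e-16, 2.9e-11 and 8e-16, and adjusted p = 0.12, 0.28 and 0.18 with an estimated correlation). Mesenchymal transcription factors fell in 15, 8 and 16 of 19, or 15, 8 and 17 adjusted over the list alone (adjusted p = 5.8e-06, 0.0029 and 8.9e-07, and adjusted p = 0.12, 0.28 and 0.18 with an estimated correlation). Snai2 was at 5.33, 9.96 and 4.60 CPM against 76.8, 78.8 and 71.3. Acta2 fell by log2 fold changes of -6.98, -6.49 and -7.28. The intestinal regulator Cdx2 and the gastric gene Gkn2 had no counts at 48 h, and Cdx2 was at least 2370-fold, 980-fold and 1710-fold and Gkn2 at least 5440-fold, 9000-fold and 11600-fold higher in iHep cells. Villin (Vil1), an actin bundler of brush borders, rose by 10.19, 8.90 and 10.38.

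Genes of cholesterol and fatty acid synthesis fell from 48 h to iHep in 4, 20 and 3 of 24, or 4, 20 and 2 adjusted over the list alone, and 1 rose with Foxa3, or 0, called with Foxa1 and Foxa2 (adjusted p = 0.045 and 6e-07, and adjusted p = 0.67 and 0.35 with an estimated correlation). Proliferation genes fell in 4, 9 and 7 of 26, or 0, 9 and 4 adjusted over the list alone, and 1 rose with Foxa2, called with Foxa2 and Foxa3 (adjusted p = 0.031 and 0.036, and adjusted p = 0.62 and 0.69 with an estimated correlation). The spindle gene Tpx2 went from 150, 150 and 143 CPM to 71.1, 67.1 and 52.1 CPM. The p53 regulator Mdm2 rose by 2.33, 2.88 and 2.87 and Egr1, an immediate early gene, by 3.09, 4.10 and 2.90. With Foxa2, 4 other lists were called, interferon genes (10 of 25 higher, adjusted p = 0.0016), stress genes (9 of 18 higher, 1 lower, adjusted p = 0.018), lung genes (7 of 9 higher, adjusted p = 0.029) and leukocyte genes (9 of 16 lower, 1 higher, adjusted p = 0.016) (adjusted p = 0.53, 0.47, 0.45 and 0.45 with an estimated correlation). With Foxa1 and Foxa3 about as many stress genes were higher (9 and 8, adjusted p = 0.093 and 0.27) and leukocyte genes lower (9 and 8, 0.05 and 0.085), so neither is shown to be particular to Foxa2. Whether the change from 48 h to iHep differed between factors was tested as an interaction. edgeR called 0 genes for each pair of factors. At an unadjusted p under 0.05 there were 835, 599 and 2152 for Foxa1 against Foxa2, Foxa1 against Foxa3 and Foxa2 against Foxa3. DESeq2 called 4, 5 and 156. With edgeR even the delivered Foxa genes were not called, so 0 calls do not show that the changes were alike. Without 48h_Foxa1 replicate 1 or 2 Tpx2 lost its Foxa1 call, at log2 fold changes of -1.10 and -1.06. Its Foxa2 call ended with these 2 groups alone (0.0942). Of the genes called with Foxa2, 3637 were also called in the same direction with a term for the set.

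The distance left between iHep cells and adult hepatocytes was measured against Hep. Alb was at 491 ± 610, 237 ± 451 and 54.9 ± 56.6 CPM against 140000 ± 12620, and apolipoprotein E (Apoe) at 383, 426 and 274 CPM against 91220 ± 16880. Apoa1 did not pass the test against Hep (11980, 3563 and 16100 CPM against 6414 ± 903, adjusted p = 0.23, 0.25 and 0.088). Hnf4a was lower in iHep_Foxa1 and iHep_Foxa2 (log2 fold changes -1.46 and -2.41), and in iHep_Foxa3 it was at 865 ± 340 CPM against 1006 ± 91.8 (adjusted p = 0.76). Its call in iHep_Foxa1 ended without Hep replicate 1 or 2 (adjusted p from 0.0767 to 0.125), with a replicate block (0.112) and with limma on FPKM (0.281). The delivered Foxa gene exceeded its Hep level by 5.18, 4.25 and 3.10, and the Foxa genes not delivered averaged at most 0.532 CPM against 37.9, 104 and 157 CPM for Foxa1, Foxa2 and Foxa3 in Hep.

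Against Hep, 9912 genes differed in iHep_Foxa1 (5820 higher, 4092 lower), 10000 in iHep_Foxa2 (5804 and 4196) and 10221 in iHep_Foxa3 (5818 and 4403). Hepatic transcription factors were lower in 18, 19 and 19 of 21 members, with Cebpa lower by log2 fold changes of -4.58, -3.96 and -5.60 and Ppara by -6.64, -7.03 and -5.47. Plasma proteins were lower in 24 of 25 members in each group, coagulation and complement genes in 27 of 28, lipoprotein genes in 17, 18 and 17 of 19, bile acid genes in 16 of 16 and xenobiotic genes in 23 of 23. Amino acid and urea genes were lower in 25 of 26, glucose genes in 11 of 11, and fatty acid oxidation genes in 11 of 12 with 1 higher. All of these list calls held with an estimated correlation (highest adjusted p = 0.016). Cps1 stood at 0.752, 0.562 and 0.197 CPM against 8754 ± 2394, Ass1 was lower by -9.04, -8.29 and -8.76, the ornithine carrier Slc25a15 by -5.61, -5.94 and -5.51 and the fructose kinase Khk by -5.84, -5.50 and -6.30. Pck1 stood at 0.172, 0.0419 and 0.0677 CPM against 9064 ± 1208. Fgb stood at 1848, 105 and 2092 CPM against 9840. In iHep_Foxa3 its call ended with limma on FPKM (0.0923) and with the low set alone (0.0937), where that group is 1 library and the log2 fold change went from -2.23 ± 0.67 to -3.03 ± 1.40. Itih1 had no counts in iHep cells, at least 93100-fold, 77700-fold and 115000-fold lower.

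Cholesterol and fatty acid synthesis genes were lower than in Hep in 23 of 24 in each group and higher in 1, 0 and 1 (adjusted p = 2.3e-11, 2.8e-13 and 4.5e-09, and adjusted p = 0.12, 0.074 and 0.14 with an estimated correlation). Scd1 was at 166, 165 and 292 CPM against 12290 and Hmgcs1 was lower by -3.59, -4.68 and -3.69. Fetal liver genes were higher in 9, 8 and 9 of 10 and lower in 0, 1 and 1 (adjusted p = 0.00082, 0.0056 and 0.0023, and adjusted p = 0.051, 0.084 and 0.069 with an estimated correlation). The RNA-binding protein gene Igf2bp3 was at 61.7, 53.0 and 63.4 CPM against 0.247, Igf2bp1 had no counts in Hep and was at least 277-fold, 276-fold and 344-fold higher, and Igf2 stood at 460 ± 386, 1079 ± 935 and 195 ± 162 CPM against 1.47. Proliferation genes were higher in 25 of 26 (adjusted p = 2.7e-11, 1e-09 and 2.9e-09, and adjusted p = 0.13, 0.17 and 0.19 with an estimated correlation), Mki67 by 5.59, 5.01 and 5.21. Cell-cycle inhibitors were higher in 8, 9 and 9 of 12 and lower in 1, 0 and 1 (adjusted p = 0.011, 0.0034 and 0.0082, and adjusted p = 0.13, 0.074 and 0.12 with an estimated correlation), Cdkn1a by 6.17, 6.04 and 6.26.

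Lists for other liver cells differed from Hep in both directions. Cholangiocyte genes were higher in 8, 8 and 7 of 13 and lower in 3, 4 and 4, without a call (adjusted p = 0.32, 0.36 and 0.47). Leukocyte and Kupffer cell genes were lower in 15 of 16 and higher in 1, and endothelial genes lower in 12, 14 and 12 of 15 (adjusted over the list alone 1 endothelial gene was also higher in iHep_Foxa3). The endothelial calls held with an estimated correlation and the leukocyte calls (adjusted p = 4e-08, 8.7e-08 and 1.1e-07) did not (adjusted p = 0.051, 0.059 and 0.062 with an estimated correlation). Stellate genes were lower in 3, 5 and 4 of 10 (adjusted p = 0.03, 0.026 and 0.027, and adjusted p = 0.12, 0.074 and 0.08 with an estimated correlation). Colec11 was at 0.158, 0.428 and 0.369 CPM against 37.5. Mesenchymal transcription factors were higher in 12, 13 and 12 of 19 and lower in 1 each, called in iHep_Foxa1 and iHep_Foxa2 (adjusted p = 0.049 and 0.01, and adjusted p = 0.35 and 0.20 with an estimated correlation). Twist1 was at 32.7, 37.3 and 43.8 CPM against 0.310. Matrix genes were called higher in iHep_Foxa2 (15 of 26, with 2 lower, adjusted p = 0.041, and adjusted p = 0.63 with an estimated correlation). Introduced factors were called lower there (adjusted p = 0.035, and adjusted p = 0.074 with an estimated correlation) and interferon genes lower in iHep_Foxa3 (14 of 25, with 4 higher, or 5 adjusted over the list alone, adjusted p = 0.041, and adjusted p = 0.72 with an estimated correlation). Epithelial genes went both ways without a call (adjusted p = 0.18, 0.50 and 0.67), with Cdh1 higher by 3.84, 3.86 and 3.29.

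The last comparisons asked whether iHep cells made with different Foxa proteins differ. With group as the only term iHep_Foxa2 and iHep_Foxa3 differed in the most genes (5139, against 1811 and 1373 for the other pairs), and with a term for the library set iHep_Foxa1 and iHep_Foxa3 did (2074, against 800, and 155 for iHep_Foxa1 with iHep_Foxa2). In iHep_Foxa2, Hnf4a was lower (189 ± 124 against 865 ± 340 CPM), as were the liver genes Serpinf2 (1.83 against 206 CPM), Fgb (105 against 2092 CPM) and Apoa1 (3563 against 16100 CPM). Ifit3, an interferon-induced gene, was higher (165 ± 200 against 6.48 ± 5.21 CPM), and so was Irf9, which mediates interferon signals (61.0 ± 20.4 against 17.6 ± 4.71 CPM). The collagen gene Col5a1 stood at 499 ± 204 against 21.0 ± 5.70 CPM.

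Between iHep_Foxa2 and iHep_Foxa3, 5139 genes differed, 2643 higher and 2496 lower in iHep_Foxa2. Cholesterol and fatty acid synthesis genes were lower in 19 of 24 and higher in 1, or 21 and 1 adjusted over the list alone (adjusted p = 1.2e-09), with Mvd at 5.13 against 42.5 CPM and Sqle at 41.1 against 155. Lipoprotein genes were lower in 8 of 19 and higher in 1, or 9 and 1 adjusted over the list alone (adjusted p = 0.003). Interferon genes were higher in 18 of 25 and lower in 1, or 22 and 1 adjusted over the list alone (adjusted p = 4.7e-07). Matrix genes were higher in 10 of 26, or 11 (adjusted p = 0.00072), mesenchymal transcription factors in 8 of 19, or 11 with 1 lower (adjusted p = 0.01), and stress genes in 8 of 18 with 1 lower, or 11 and 1 (adjusted p = 0.0058), each second count adjusted over the list alone. None of these list calls held (adjusted p = 0.55 with an estimated correlation for lipoproteins and adjusted p = 0.73 with an estimated correlation for each of the other 5). The surfactant gene Sftpd was at 18.2 ± 20.1 against 0.0664 CPM, and C3 of complement at 399 ± 116 against 24.0 ± 16.9 CPM. All 4 iHep_Foxa2 libraries belong to the low set and 5 of 6 iHep_Foxa3 libraries to the high set. With a term for the set 800 genes were called, 573 of them in the same direction as without it, and the calls of Hnf4a, Apoa1, Sqle, Col5a1, Sftpd and C3 ended (adjusted p from 0.0707 to 0.562). Their log2 fold changes shrank from -2.19 ± 0.51 to -1.33 ± 0.53 (Hnf4a), -2.18 ± 0.53 to -0.56 ± 0.36 (Apoa1), -1.91 ± 0.36 to -1.03 ± 0.39 (Sqle), 4.57 ± 0.75 to 1.76 ± 0.82 (Col5a1), 7.99 ± 1.49 to 6.45 ± 1.96 (Sftpd) and 4.06 ± 0.91 to 1.51 ± 1.32 (C3). The calls of Serpinf2, Fgb, Mvd, Ifit3 and Irf9 did not end. With the low set alone iHep_Foxa3 is 1 library, so effect sizes alone are given. There log2 fold changes of C3 (6.96 ± 1.67), Col5a1 (4.70 ± 1.11) and Sftpd (8.02 ± 3.96) were no smaller than with all libraries. Those of Irf9 (1.74 ± 0.45), Fgb (-3.59 ± 0.94) and Ifit3 (3.31 ± 1.56) were smaller (1.80, -4.31 and 4.67 with all libraries). So were those of Mvd (-1.47 ± 0.37), Sqle (-0.37 ± 0.39), Apoa1 (-1.08 ± 0.48) and Hnf4a (-1.52 ± 0.83). Resting on 1 library, these values do not decide about the library set.

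iHep_Foxa1 and iHep_Foxa2 differed in 1811 genes, 1172 higher and 639 lower in iHep_Foxa1. Enpp3, a nucleotide phosphodiesterase of bile duct and gut, was at 34.1 ± 10.9 CPM in iHep_Foxa1 and 1.22 ± 0.706 in iHep_Foxa2, and kept its call with only these groups fitted and with a term for the set. Hnf4a did not pass (367 ± 194 against 189 ± 124 CPM, adjusted p = 0.18). Fgb (1848 against 105 CPM) and Serpinf2 (132 against 1.83 CPM) were higher in iHep_Foxa1, and Irf9 was lower (25.3 against 61.0 CPM). Cholesterol and fatty acid synthesis genes were higher in 10 of 24, or 16 adjusted over the list alone (adjusted p = 2.9e-08, and adjusted p = 0.36 with an estimated correlation). Fdft1 was at 88.9 against 23.4 CPM. Interferon genes were lower in 16 of 25, or 18 adjusted over the list alone (adjusted p = 1.6e-09, and adjusted p = 0.36 with an estimated correlation). Plasma proteins, lipoproteins and fatty acid oxidation genes were higher in 5 of 25, 4 of 19 and 3 of 12, or 5, 7 and 3 adjusted over the list alone with 1 lipoprotein gene lower (adjusted p = 0.013, 0.0061 and 0.0061, and adjusted p = 0.36 for all 3 with an estimated correlation). Intestinal genes were higher in 4 of 16, or 5 adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.38 with an estimated correlation). Matrix genes, mesenchymal transcription factors and proliferation genes were called with 1, 2 and 0 members past the threshold, or 0, 2 and 0 adjusted over the list alone, and for proliferation 4 genes at an unadjusted p under 0.05 and 1 with DESeq2 (adjusted p = 0.0045, 0.0061 and 0.015, and adjusted p = 0.52, 0.36 and 0.70 with an estimated correlation). With these groups alone 3 genes were called, with a term for the set 155 and with low-set libraries alone 4. The named calls other than Enpp3 ended with these groups alone (adjusted p = 0.189). Their log2 fold changes were then 6.26 ± 1.23 (Serpinf2), 4.19 ± 0.85 (Fgb), 2.00 ± 0.50 (Fdft1) and -1.23 ± 0.31 (Irf9), against 6.18 ± 0.94, 4.13 ± 0.70, 1.93 ± 0.42 and -1.27 ± 0.26 with all groups fitted. The low set alone ended them too (0.262 to 0.338, at 4.97, 3.77, 1.10 and -1.01). The calls of Fdft1 and Irf9 ended with the set term (0.0942 and 0.0643), where the log2 fold change of Fdft1 shrank to 1.07 ± 0.32 and that of Irf9 moved by less than 0.2. The call of Fdft1 also ended with a replicate block (0.0728). Leaving out iHep_Foxa1 replicate 1, 3, 4, 5 or 6 gave 3124, 3464, 884, 592 or 706 genes, and leaving out iHep_Foxa2 replicate 1, 3 or 4 gave 1083, 543 or 301.

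iHep_Foxa1 and iHep_Foxa3 differed in 1373 genes, 727 higher and 646 lower in iHep_Foxa1. Higher in iHep_Foxa1 were the adhesion gene Epcam at 93.8 ± 102 against 7.76 ± 2.50 CPM, Krt8 at 1207 ± 1031 against 251 ± 80.6 CPM and F11r at 350 ± 57.7 against 232 ± 27.2 CPM. Lower there were Trf (376 ± 247 against 1830 ± 674 CPM) and the collagenase gene Mmp13 (39.3 ± 41.0 against 592 ± 347 CPM). Scin, an actin-severing protein, was at 41.6 ± 42.2 against 0.761 ± 0.445 CPM, and Hnf4a did not pass (367 against 865 CPM, adjusted p = 0.07). Epithelial genes were higher in 11 of 30 and intestinal genes in 4 of 16 (adjusted p = 0.00029 and 0.0041), the latter including Lgals4 (756 against 93.9 CPM) and the antimicrobial lectin Reg3g (170 ± 165 against 8.32 ± 10.2 CPM). Proliferation genes were called higher with 1 of 26 past the threshold, Pcna at 171 against 107 CPM, and cholesterol genes lower with 1 higher and 1 lower, or 1 and 2 adjusted over the list alone. Their adjusted p was 0.0038 and 0.0024. All 4 list calls ended (adjusted p = 0.86 with an estimated correlation). With these groups alone 83 genes were called, Mmp13 and Scin among them, and the calls of Trf, Epcam, Krt8, F11r, Lgals4, Reg3g and Pcna ended (adjusted p from 0.059 to 0.0771). All 9 kept their calls with the high set alone and with a set term (highest adjusted p = 0.0205 and 0.0201). With the low set alone, where iHep_Foxa3 is 1 library, the calls of all 9 ended (0.096 to 0.631) with larger standard errors. The log2 fold changes of Epcam (3.79 ± 2.39), Krt8 (2.92 ± 1.45), Lgals4 (3.75 ± 1.89), Reg3g (6.67 ± 3.56) and Mmp13 (-4.31 ± 1.03) were then as large as with all libraries (3.60, 2.26, 3.01, 4.35 and -3.91). Those of Scin (5.26 ± 1.73), Trf (-1.92), Pcna (0.65 ± 0.37) and F11r (0.38 ± 0.33) were smaller (5.77, -2.28, 0.68 and 0.60 with all libraries). With a replicate block the call of Reg3g ended (0.13, at 3.80 ± 1.53). Leaving out iHep_Foxa1 replicate 2 or iHep_Foxa3 replicate 1, 4 or 5 gave 874, 2344, 719 or 754 genes, and Hnf4a passed without iHep_Foxa1 replicate 5 or iHep_Foxa3 replicate 1 (0.0320 to 0.0446).

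Calls against MEF overlapped between factors. At 48 h, 289 genes were higher and 428 lower with all 3 factors, where independence would give 0.172 and 0.504. Independence does not allow for the library set, which differs here, and with a term for it 227 and 236 genes were shared. In iHep cells 1834 genes were higher and 2014 lower with all 3, where independence would give 115 and 120, and 1330 and 1594 of these changed at least 2-fold in each. All of these comparisons share the same MEF libraries. Of the genes that rose at 48 h, 117, 125 and 132 with Foxa1, Foxa2 and Foxa3 were also higher in Hep than in MEF (85.45, 88.1 and 89.1 by independence), and 121, 120 and 115 were lower in Hep. Adding a set term left 73, 84 and 86 that were higher in both. Of the genes that fell at 48 h, 177, 187 and 173 were also lower in Hep, where independence would give 168, 176.5 and 160.5, and 125, 127 and 120 were higher there. With that term 101, 110 and 108 were lower in both. Of the genes that rose in iHep cells, 1447, 1080 and 1542 were also higher in Hep (800, 611 and 918 by independence) and 536, 458 and 720 were lower there. Mutant and 48h_Foxa3 cells shared 240 higher and 338 lower genes against MEF (28.6 and 39.6 by independence), and 145 and 141 with a term for the set.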

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

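The tests of the leukocytes in the MEF cultures and of another source for the mutant cells were chosen after the result was seen, as was the definition of the library sets behind the tests that use them.

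Between iHep_Foxa2 and iHep_Foxa3, 4534 of 5139 called genes (88.2%) went the way low differs from high inside iHep_Foxa1. That fits library sets as 1 source of the calls. It also fits Hnf4a, lower in iHep_Foxa2 and at 108 to 314 CPM in low and 363 to 670 in high iHep_Foxa1 libraries. With a set term 573 calls kept their direction. Of 100 divisions of these libraries the real 1 called most, and the highest other called 2672, so a chance division is excluded here. The others above 2000 also follow the library set, as 4 of them (2057 to 2672) have low-set libraries alone in the smaller group and the fifth (2220) high-set libraries alone. The Foxa protein and the library set cannot be told apart for the calls that ended.

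The mutant cells differed from 48h_Foxa3 in 491 genes, of which 241 (49.1%) went the way low differs from high inside iHep_Foxa1. The mutant is low by Rn7sk but not by Rps29, so this share cannot decide on the library set. Leaving out the introduced factors, 431 of 489 (88.1%) went the way iHep_Foxa3 differs from 48h_Foxa3. Both subtract the same 48h_Foxa3 libraries, which makes signs agree without a shared effect. So the 88.1% decides nothing about the level of introduced factors or a later stage. All 4 Y-linked genes were above 10 CPM in both mutant libraries and below 1 CPM in every other library, which fits cells of another source. An effect of the deletion itself was not separable from these, as no library holds full-length Foxa3 in the same cells.

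Leukocyte genes were lower at 48 h than in MEF, 5 of 16 with each factor. All 12 (100%) of the leukocyte genes above 1 CPM in a MEF library were higher in MEF replicate 2, by 3.6 to 14.4 times, which fits leukocytes in the MEF cultures. Without MEF replicate 1 the fallen genes numbered 4, 5 and 5, and without MEF replicate 2 they numbered 1, 1 and 1. A library set difference could not be decided, since the median log2 fold change of the 5 genes went from -5.18 to -5.89 (113.6%) with the set term while iHep cells, which inform that term, hold a median of 0.00861 CPM. No biological explanation was tested.

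For iHep_Foxa1 and iHep_Foxa2, 4 of 100 divisions of the libraries, the real 1 included, called at least the real 1811 genes. The 3 others each put all 3 high-set libraries on one side. With these libraries in the smaller group 4350 and 4296 genes were called, which fits a set effect. With them in the larger group, as in the real division, the other counts ran from 0 to 2508. With a term for the set the real division called 155. For iHep_Foxa1 and iHep_Foxa3 it was 7 of 100, with 3011 as the highest other against the real 1373. Of the 6 others 5 put all 4 low-set libraries on one side, so those 5 follow the library set. This count does not by itself exclude a chance division. The real division called 2074 with a term for the set and 2532 with the high set alone. For iHep_Foxa2 and iHep_Foxa3 it was 1 of 100.

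Single libraries lay far from the others of their group in 6 of 90 cases tested over 30 measures, where chance would give about 1 in 20 (5%). As mean log2(CPM + 1) of a gene list, iHep_Foxa2 replicate 1 was at 2.04 for xenobiotic genes (others 1.63 to 1.68) and at 6.85 for cell-cycle inhibitors (others 6.29 to 6.37). Replicate 2 of that group was at 6.54 for epithelial genes (others 4.21 to 4.58) and 4.27 for matrix genes (others 5.48 to 5.70), and replicate 4 at 6.29 for stress genes (others 7.04 to 7.15). In iHep_Foxa1 replicate 3 the erythroid genes were at 0.70 (others 0.20 to 0.29).

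Reads assigned to no transcript were a larger share than in MEF (14.7% to 14.9%) in 5 groups. They averaged 21.7% in iHep_Foxa1 (18% to 26.6%), 20.9% in iHep_Foxa2 (19.4% to 22.7%), 21.9% in iHep_Foxa3 (19.4% to 24.4%), 33.8% in Hep (30.9% to 36.8%) and 18.4% with the mutant (18.1% to 18.7%).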

How the results depend on the processing

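The tests with a library set term, with the libraries of 1 set alone and with 48 h and MEF libraries alone were chosen after the result was seen. DESeq2 size factors, no filter on low counts and the most abundant transcript alone left every count of called genes within 1.5 times. Counts that moved further are given here, and the cause was not tested unless stated.

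For 48h_Foxa1, 48h_Foxa2 and 48h_Foxa3 against MEF the DESeq2 Wald test called 2102, 2102 and 2064 genes, the compared groups alone 5697, 5738 and 5810, limma on FPKM 2078, 2102 and 2096, and 48 h and MEF libraries alone 8766, 8789 and 8744. A set term gave 529 for Foxa1. Without 1 library the counts ran from 13 to 133, 17 to 124 and 18 to 134, where fewer samples leave 1 library that is assumed to vary like the other groups.

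With a replicate block the counts were 1738, 1769 and 1782 for those comparisons, 779 for the mutant against 48h_Foxa3, 2 for 48h_Foxa1 against 48h_Foxa2 and 228 for iHep_Foxa1 against iHep_Foxa2. Replicate numbers did not pair samples, as correlations of matched libraries ran from -0.18 to 0.21.

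For 48h_Foxa1 against 48h_Foxa2 the count of 1 became 2 with the Wald test, the groups alone, FPKM, a set term, high-set libraries alone and 48 h with MEF alone, and 0 without any 1 library. Without 1 library the other 48 h pairs held 1 to 2 and 1 genes.

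For the mutant against 48h_Foxa3 the Wald test called 1284, the groups alone 9853, FPKM 1288, a set term 3810, 48 h and MEF alone 7668 and iHep_Foxa3 as comparator 5387, with 49 to 83 without 1 library. Against MEF the mutant gave 7276 with the groups alone, 4829 with a set term and 9921 with 48 h and MEF alone, and 725 to 1330 without 1 library.

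iHep_Foxa1 against MEF gave 3506 with the groups alone and iHep_Foxa3 3990 with the low set alone. Without 1 library the counts against MEF ran from 3930 to 7201, 2905 to 4669 and 4858 to 8345. iHep_Foxa1 against 48h_Foxa1 gave 4223 with the groups alone, and without 1 library the counts against 48 h ran from 4046 to 7125, 3647 to 6355 and 4083 to 6717.

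iHep_Foxa1 against iHep_Foxa2 gave 3105 with the Wald test, 3 with the groups alone, 155 with a set term and 4 with the low set alone, and 301 to 3464 without 1 library. iHep_Foxa1 against iHep_Foxa3 gave 2257, 83, 2074 and 58, and 2532 with the high set alone, and 719 to 2344 without 1 library. iHep_Foxa2 against iHep_Foxa3 gave 800 with a set term and 279 with the low set alone.

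Of 588 list tests 176 were called with the preset correlation, 162 with a block, 160 with a set term and 43 with an estimated correlation. Of 339 gene and comparison pairs named, 331 were past the threshold, 295 of them under every alternative chosen beforehand that leaves no library of the compared groups out and 274 without each library in turn. The 1 that reversed was Foxa2 in iHep_Foxa2 against 48h_Foxa2, at a log2 fold change of -0.46 with a set term. This reversal decides nothing, as the libraries that inform the term hold at most 0.67 CPM of Foxa2.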

Other observations

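The tests in this part were chosen after the result was seen, and they describe levels only.

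Trace levels of hepatocyte transcripts were spread over more genes in MEF than in the 48 h cells, while the upper quartile was higher at 48 h. Over 78 liver genes with at least 1000 CPM in Hep, the first quartile in MEF replicates 1 and 2 was 47.7 and 71.2 per 1000000 of the Hep level, the median 79.8 and 89.7 and the third-quartile value 184 and 190. Transcripts were seen from 74 and 78 of the 78 genes. In the 48 h libraries with full-length factors 51 to 54 of the genes were seen, the first quartile was 0 and the medians ran from 21.9 to 30.2 and the third-quartile value from 299 to 494, and in the mutant libraries the medians were 33.9 and 30 and the third-quartile values 416 and 469. An earlier gene set for this measure, chosen in part by 48 h level, was replaced by this one.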
